A study of Mus musculus with 8 samples.

How the data were processed

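Gene expression was measured by bulk RNA sequencing in 8 libraries of mouse cells sorted for tdTomato fluorescence from molars of the lower jaw at postnatal day 10, after tamoxifen at day 3. Per the labels, the sorted cells are CXCL12-positive cells of the apical papilla, the soft tissue at the tip of the growing tooth root. Of the libraries, 4 carry 1 deleted copy of Ctnnb1, the gene for beta-catenin (cHet), and 4 carry a deletion of both copies (cKO). Low-input cDNA was made with a SMART-Seq v4 kit, per the labels' protocols, which amplifies full-length transcripts without marking their strand or tagging single molecules.

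The values used are the authors' deposited whole-number counts per gene, with Ensembl gene identifiers, and were not normalized. The submitters' processing notes name Trim Galore, STAR and the genome builds GRCm39 and mm39. The counting tool, the annotation and all versions are not given in the sources used here. Identifiers were matched without their version suffix to the symbols of a mouse gene name table, and 52073 of the 56748 genes matched a symbol. Coordinates were not used here. Where several identifiers shared a symbol, the one with the largest total count stood for it. Counts of near-identical genes, such as members of the olfactory receptor family, are uncertain because the handling of shared reads is not given in the sources used here.

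The columns of the table are named by group and by an animal-like or sample-like number (cHet8, cHet11, cHet12, cHet14, cKO7, cKO9, cKO14 and cKO15), and these numbers match none of the sample titles. Each column was therefore assigned to its group only. The labels do not say whether the libraries came from separate animals, so the p-values measure the spread between these libraries, which may be technical. Total counts lay between 44444033 and 50051392 per library, and the common biological coefficient of variation was 0.553. Whether depth or the spread between libraries limits precision was not tested.

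The groups were compared in R 4.3.3 with edgeR 4.0.16, using trimmed-mean (TMM) factors, the default expression filter by group, which kept 21508 genes, and the quasi-likelihood F test with genotype as the sole term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and called genes are those of this edgeR fit unless another is named. All tests were two-sided. Normalised counts are CPM scaled with TMM factors, given as mean ± SD over 4 libraries. The standard error of a log2 fold change was taken as the size of the fold change divided by the square root of its F statistic, which is an approximation. Single values per library were compared with an exact permutation test over the 70 assignments of 4 against 4 libraries, whose smallest two-sided p is 0.0286. List scores are means of log2 CPM, with a prior count of 2, over the tested members of a list.

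Before the data were examined, 36 gene lists were fixed, covering signalling pathways, differentiation states, cell processes and markers of other cell types. They were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01, and again with the correlation estimated. The fry test, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes, was run beside it. Adjusted p-values of lists are over the 36 lists. For each list, member genes were also adjusted over the list alone. After the data had been seen, 4 further marker lists were added: olfactory sensory neurons, supporting cells and glands of the olfactory epithelium, general mesenchyme and ameloblasts.

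Named genes followed a rule fixed before the data were examined. Ctnnb1 and Cxcl12 were always given. Then came the 12 genes with the largest rises and the 12 with the largest falls among called genes with a mean of at least 5 CPM, groups that did not overlap and a symbol that is not a predicted name. From each list, up to 4 members with the smallest p were eligible. Lef1, Nkd1, Tac1, Prrx1, Ptpru, Megf6, Lum, Ambn, Amelx and the olfactory and sex-linked genes are named outside this rule and were chosen after their values were seen.

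The analysis was tested on simulated counts for 21508 genes with known changes in 4 against 4 libraries, of which 20557 passed the filter. Of the changed genes, 62% of those with 4-fold and 87% of those with 16-fold changes were recovered, and 7 of 159 calls were false. The changed genes had a mean of at least 1 CPM, and the simulated counts varied independently between genes. Variation that many genes share between libraries was not simulated, so these rates may not hold for the real counts. Other fits fixed before the data were examined were DESeq2 1.42.0, limma voom with quality weights, RLE factors, library size alone, no filter, a filter of 1 CPM in 4 libraries, robust dispersions, a threshold of 0.10, a test against a 1.5-fold change, omission of the mitochondrial genes with the 20 most abundant genes, omission of sex-linked genes, and omission of each library in turn. Alternatives chosen after seeing the data were a covariate for the olfactory neuron score, scaling to or a covariate for the general mesenchyme score, and omission of 2 pairs of libraries. Fits with a term for the replicate number were left out because the columns do not carry those numbers.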

Results

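Transcripts were counted in 8 libraries of sorted tdTomato-positive cells from the apical papilla of mouse molars, 4 labelled cHet and 4 labelled cKO for Ctnnb1. Total counts were 47869800 ± 1790950 in cHet and 46093200 ± 1402310 in cKO (SD, n = 4 each, exact p = 0.171). Between 25146 and 30308 genes had at least 1 count, the fewest in cKO15 and the most in cHet11. Correlations of log2 CPM lay between 0.882 and 0.942 within groups and between 0.858 and 0.943 across groups, so no pair of libraries looked like a repeat of the other. The closest pair of all crossed the groups, cHet11 and cKO9 (0.943). cKO9 also correlated more with cHet14 (0.930) than with its closest cKO library, cKO14 (0.926). Over the 500 most variable genes the leading component carried 27.2% of the variance and did not separate the groups (exact p = 0.429). Over all tested genes the leading component carried 27.3% and did separate them (exact p = 0.0286, the smallest possible). The X-inactivation transcript Xist and the Y-linked gene Ddx3y were both detected in all 8 libraries, Xist between 19.2 and 121 CPM and Ddx3y between 8.14 and 60.3 CPM. Xist stood at 60.5 ± 41.9 CPM in cHet and 30.5 ± 10.8 in cKO (exact p = 0.143). Ddx3y stood at 28.9 ± 19.0 and 49.1 ± 12.4 CPM (exact p = 0.114). Sex was not a term in any fit.

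The targeted gene was examined first. Ctnnb1 (ENSMUSG00000006932.18) stood at 257 ± 40.2 CPM in cHet and 277 ± 39.2 CPM in cKO, a log2 fold change of 0.11 (SE 0.15, adjusted p = 0.785, exact p = 0.486). The lowest of the 8 libraries was cHet12 with 209 CPM and the highest cKO14 with 313 CPM. The sign of this small difference turned under the mesenchyme scaling, with a log2 value of −1.20 (adjusted p = 0.0531) when the median of all tested genes stood at −1.30. The count of the whole gene was thus not lower in the libraries labelled cKO, and the group names used throughout are those of the labels. The labels do not name the deleted exons, and the counts are sums over each gene, so reads from exons outside the deletion are included and the count cannot check the labels.

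Libraries labelled cKO held a larger share of transcripts of the gene that names the sorted cells. Cxcl12 (ENSMUSG00000061353.12), the chemokine that marks this papilla population, rose from 149 ± 91.5 to 826 ± 238 CPM, 5.54-fold (log2 2.47, SE 0.46, adjusted p = 0.0497), and had a log2 value of 1.25 (adjusted p = 0.401) with the mesenchyme score as covariate. Bmp2, a secreted bone morphogenetic protein, rose from 70.4 ± 38.3 to 772 ± 234 CPM, 11-fold (adjusted p = 0.0328). Kif26b, a kinesin-family protein, had the smallest adjusted p of the genes named here, with a rise from 5.54 ± 1.97 to 76.0 ± 19.0 CPM (adjusted p = 0.00792).

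The largest rises were those of Plpp4, a lipid phosphatase, from 0.574 to 15.6 CPM (log2 4.76), and Slc5a7, the high-affinity choline transporter, from 1.65 to 32.0 CPM (log2 4.27). Angpt4, a ligand of the Tie2 receptor, rose from 36.2 to 665 CPM (log2 4.2) and the hormone subunit gene Gpha2 from 15.1 to 269 CPM (log2 4.16). Col25a1, a transmembrane collagen, had a log2 change of 3.87, Ifitm10 and the substance P receptor gene Tacr1 both 3.72, the calcium channel subunit gene Cacna2d3 3.64, Tmem100 3.35 and the synaptotagmin gene Syt6 3.34. Of all tested genes, 10.1% had groups that did not overlap, where chance gives 2.86%. Without cHet8 the log2 change was 5.28 for Slc5a7 and 4.02 for Syt6. Among the 12 genes that fell, 7 were eligible to be named. Coch, an extracellular matrix protein known from the inner ear, fell from 282 ± 103 to 92.2 ± 19.9 CPM (log2 −1.61, adjusted p = 0.04997), and the collagen gene Col24a1 had a log2 change of −1.27. Cdca8, a mitotic chromosome protein, fell by 1.0 on the log2 scale, Cyb5r4 by 0.73 and the serpin gene Serpini1 by 0.67. The olfactory receptor genes Olfr309 and Olfr116 fell by 1.22 and 1.21, and reads of this large family may be shared between its members. Transcripts of the olfactory epithelium stood lower in cKO alongside these changes and general mesenchymal markers higher, as given with the cell type markers. 

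**Figure D1:**
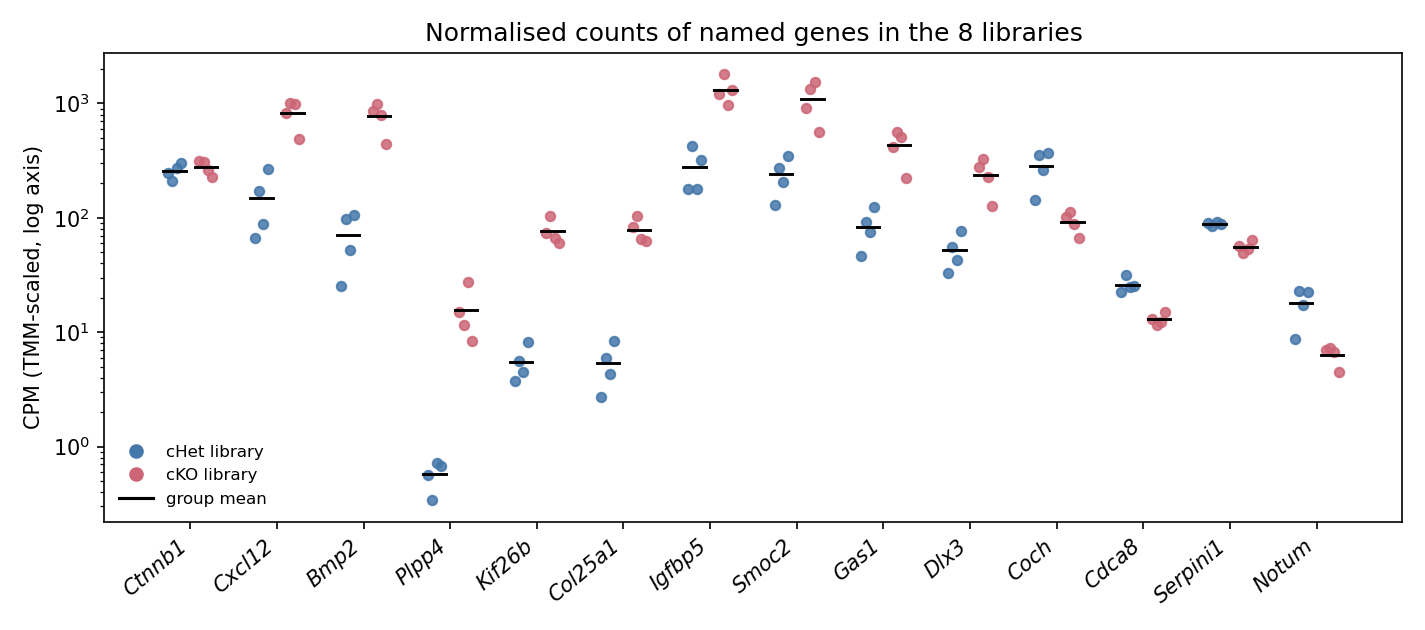
Normalised counts (CPM, log axis) of 14 genes in each library, with points for libraries coloured by group and a bar at each group mean. Ctnnb1 overlaps between groups, Cxcl12 lies between 66.4 and 268 CPM in cHet and between 491 and 1001 CPM in cKO, and Coch, Cdca8 and Serpini1 lie lower in every cKO library than in any cHet library.

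Of 21508 tested genes, 232 were higher and 12 lower in cKO, so 95.1% of the 244 calls were rises. With libraries scaled to mesenchymal genes, 5 genes were higher and 4 lower, a share of 55.6% rises. The number of called genes depended on the tool and on single libraries, although none of the 232 was called lower in any other fit. DESeq2 called 1704 genes higher and 853 lower (66.6% rises), the fit with the mesenchyme score as covariate 6 and 3 (66.7%), the fit with the olfactory score as covariate 0 and 0 by edgeR (1327 genes at an unadjusted p under 0.05), voom 1281 and 271, and at an unadjusted p under 0.05 edgeR gave 2320 and 1361. By chance a share of 0.05 of the 21508 tested genes has an unadjusted p under 0.05, and the 1327 genes are not far above that. Leaving out 1 library gave 4 higher and 0 lower genes without cHet11, 0 and 0 without cHet12, cHet14 or cKO14, 8 and 0 without cKO15 or cKO7, 155 and 1 without cHet8, and 816 and 144 without cKO9. For the omissions with 0 calls by edgeR, between 2934 and 3352 genes still had an unadjusted p under 0.05, and no other tool was run on them. 

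Beta-catenin acts with TCF and LEF factors to switch on a known group of target genes. With genotype as the sole term, this group showed no net shift in 1 direction. Its members had log2 values of both signs, 8 positive and 13 negative. A test of net direction cannot show that the members were unchanged. None of the 21 tested canonical Wnt targets was called over all genes (0 higher, 0 lower), and 2 were higher and 1 lower when adjusted over the list alone. Notum, a secreted Wnt-inactivating enzyme and feedback target, stood at 17.8 ± 6.66 CPM in cHet and 6.35 ± 1.28 in cKO (log2 −1.49, SE 0.34, adjusted p = 0.0801, 0.0138 adjusted over the list alone). Dkk1, a secreted Wnt inhibitor, stood at 3.14 and 22.1 CPM (log2 2.81, 0.0138 adjusted over the list alone), and the receptor gene Fzd7 at 50.2 and 141 CPM (log2 1.49). The feedback gene Nkd1 had a log2 value of −0.92 (SE 0.32) and Lef1 of 0.25 (SE 0.43), neither of which passed. DESeq2 called Notum (adjusted p = 0.000327), Dkk1 (5.10e-05), Fzd7 (4.35e-05) and Nkd1 (0.0348), and voom called Dkk1 (0.0134) and Fzd7 (0.0151) but not Notum (0.0934) or Nkd1 (0.195). Leaving out 1 library, edgeR called Dkk1 without cHet8 (log2 3.73, adjusted p = 0.0347) and without cKO9 (0.0443), and Fzd7 without cKO9 (0.0217). The list had a median log2 change of −0.24 and a mean of 0.04, so these differ in sign, and camera gave the direction down with an adjusted p of 0.785 (0.960 with an estimated correlation). In a fit with the mesenchyme score as covariate, chosen after the data had been seen, the list was lower (median −1.003, camera adjusted p = 9.20e-16, adjusted p = 0.0286 with an estimated correlation, adjusted p = 0.00897 by fry). With the olfactory score as covariate the median was −0.26 (adjusted p = 0.00847, adjusted p = 0.606 with an estimated correlation), and with mesenchyme scaling −1.47, where it was not called (adjusted p = 0.0656). 

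Wnt ligands and receptors passed camera with direction up (35 tested, median 0.34, adjusted p = 0.00223, adjusted p = 0.545 with an estimated correlation). No member was called over all genes by edgeR, while 11 were higher adjusted over the list alone. With covariates chosen after the data had been seen, the call ended with the olfactory score (median 0.22, adjusted p = 0.0993) and with the mesenchyme score, where the direction was down (median −0.0158, adjusted p = 0.214). The genes higher adjusted over the list alone included Wnt9a (9.26 to 41.9 CPM), Fzd2 (18.3 to 43.5 CPM) and Rspo4 (7.46 to 54.6 CPM), a secreted amplifier of Wnt signalling. Over all genes Wnt9a and Rspo4 each passed in 4 of 23 other fits and Fzd2 in 3. Cadherins and catenins other than Ctnnb1 gave 0 edgeR calls among 16 genes under both adjustments (adjusted p = 0.558), with Cdh11 at 291 and 871 CPM. Cdh11 passed over all genes in 4 of 23 other fits.

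In the BMP response list, which had the highest median of the 36 lists (log2 1.78), 6 of 15 tested genes were higher over all genes and 11 adjusted over the list alone, with none lower. The list passed camera with direction up (adjusted p = 7.00e-16, adjusted p = 0.228 with an estimated correlation). Besides Bmp2, the inhibitory Smad gene Smad6 rose from 26.8 ± 9.96 to 116 ± 28.1 CPM, the secreted BMP antagonist gene Nog from 2.56 ± 0.966 to 15.9 ± 2.33 CPM, and the transcription factor gene Atoh8 from 7.38 ± 3.49 to 36.8 ± 11.8 CPM. In the Hedgehog list 2 of 10 genes were higher over all genes and 8 adjusted over the list alone (median 1.21, camera adjusted p = 7.87e-10, adjusted p = 0.228 with an estimated correlation). Gas1, a Hedgehog co-receptor, rose 5.12-fold and Gli3, a transcription factor of the pathway, 3.50-fold, while the signal transducer gene Smo had a 3.32-fold higher mean without passing over all genes (adjusted p = 0.0592). TGF-beta and YAP response genes gave 1 higher gene of 11 over all genes and 7 adjusted over the list alone (median 0.88, adjusted p = 3.75e-09, adjusted p = 0.279 with an estimated correlation). Tgfb3 rose from 69.1 to 308 CPM, and Tgfbi stood at 99.4 and 525 CPM. Axon guidance and neurotrophic genes gave 2 of 24 and 9 adjusted over the list alone (median 0.56, adjusted p = 3.02e-05, adjusted p = 0.228 with an estimated correlation), with rises of Efnb1 (3.47-fold) and Slit3 (4.44-fold), both encoding guidance ligands. 

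These 4 lists were also the ones that passed fry, with adjusted p of 0.0309 for BMP response, 0.0179 for Hedgehog, 0.0436 for TGF-beta and YAP, and 0.0309 for axon guidance. With the mesenchyme score as covariate the medians were 0.82 for BMP response, 0.64 for Hedgehog, 0.52 for TGF-beta and YAP and 0.19 for axon guidance. In that fit Hedgehog passed fry (0.0111), while for the other 3 lists the adjusted p by fry was 0.119. With the olfactory score as covariate none of the 4 passed fry (adjusted p = 0.0797 for Hedgehog, 0.251 for BMP response and axon guidance, 0.318 for TGF-beta and YAP). In all, camera at the preset correlation called 16 of the 36 lists, 13 up and 3 down. None of these calls held with an estimated correlation, and 11 of the 34 other ways to split the libraries 4 against 4 called as many lists. The general mesenchyme score stood 1.25 higher in cKO on the log2 scale beside these groups (exact p = 0.0571).

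In the dental papilla and pulp list 3 of 17 tested genes were higher over all genes, and 13 were higher and 2 lower adjusted over the list alone. The list passed camera with direction up (median 1.66, adjusted p = 5.57e-13, adjusted p = 0.355 with an estimated correlation) and did not pass fry (adjusted p = 0.0730). Its median was 0.44 with the mesenchyme score as covariate (adjusted p = 0.0207, adjusted p = 0.447 with an estimated correlation). Beside Cxcl12, Igfbp5, an insulin-like growth factor binding protein, rose from 276 ± 121 to 1318 ± 348 CPM and the matrix protein gene Smoc2 from 241 ± 94.4 to 1087 ± 442 CPM. The homeobox gene Dlx2 stood at 38.2 and 152 CPM (adjusted p = 0.0572), and the neuropeptide gene Tac1 at 26.8 and 8.53 CPM (log2 −1.65, adjusted p = 0.108). In the dental follicle and periodontal ligament list 1 of 8 genes was higher, and 3 adjusted over the list alone (median 1.10, adjusted p = 4.27e-05, adjusted p = 0.455 with an estimated correlation). With the mesenchyme score as covariate its call ended (median 0.0368, adjusted p = 0.348). The called gene was Tnc, encoding the matrix protein tenascin C, which rose 7.83-fold, while Postn stood at 331 and 1499 CPM and the tendon factor gene Mkx at 23.1 and 86.3 CPM. Olfactory epithelium transcripts stood lower beside both groups, and the papilla score stood 1.41 higher in cKO (exact p = 0.0286, 0.171 adjusted over 36 lists).

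Mineralizing fates, which lie next to these cells in root formation, gave a mixed picture. In the osteoblast and cementoblast list none of 16 genes was called over all genes by edgeR and 5 were higher adjusted over the list alone, among them the matrix genes Cthrc1 (68.4 and 240 CPM) and Sparc (1383 and 3383 CPM). Over all genes Cthrc1 passed in 4 of 23 other fits and Sparc in 3 of 22. The list passed camera with a median of 0.95 (adjusted p = 2.07e-04, adjusted p = 0.545 with an estimated correlation). With the mesenchyme score as covariate its direction turned to down (median −0.12, adjusted p = 0.0207, adjusted p = 0.435 with an estimated correlation). In the odontoblast list 1 of 8 genes was called, the homeobox gene Dlx3, which rose from 52.1 ± 19.2 to 239 ± 85.3 CPM (adjusted p = 0.0377). Over the list alone 2 were higher and 1 lower. Nes, encoding the filament protein nestin, stood at 11.8 and 37.0 CPM, the sphingomyelinase gene Smpd3 at 173 and 64.1 CPM, and Dspp, encoding the main noncollagenous dentin protein, at 7.72 and 3.28 CPM (log2 −1.23, adjusted p = 0.257). The odontoblast list as a whole did not pass (median 0.05, adjusted p = 0.271, adjusted p = 0.791 with an estimated correlation). It passed with direction up without cHet8 (median 0.63, adjusted p = 0.0456) and with direction down under the mesenchyme covariate (median −0.58, adjusted p = 0.0207, adjusted p = 0.230 with an estimated correlation). The odontoblast list holds Mmp20, which is also in the added ameloblast list. Mmp20 stood at 33.2 CPM in cHet8 and at 5.97 to 10.3 CPM in the other cHet libraries. cHet8 also had the highest ameloblast score (8.62), and whether this bears on the change without cHet8 was not tested. In the chondrocyte list 0 of 16 genes were called by edgeR and 3 adjusted over the list alone, with Sox9 at 95.6 and 477 CPM and Col9a2 at 138 and 436 CPM. Over all genes Sox9 passed in 6 of 23 other fits and Col9a2 in 5. The list's median of −0.50 and mean of −0.20 were negative while camera gave the direction up (adjusted p = 0.185). It passed camera with direction up without cHet14 (median 0.97, adjusted p = 2.23e-06) and with the olfactory covariate (median 1.35, adjusted p = 0.00384). It also passed as up with negative medians without cKO9 (−0.15, adjusted p = 0.0307) and without a filter (−0.51, adjusted p = 0.0445). The same held without cHet11 and cKO9 (−0.23, adjusted p = 0.0238) and with mesenchyme scaling (−2.07, adjusted p = 0.00112). With mesenchyme scaling the median of all tested genes was −1.30, so the list's median lay below it although camera gave the direction up. Of 4 tested adipocyte genes none was called over all genes by edgeR, and 1 was higher and 1, Cd36, lower adjusted over the list alone (median −0.14, mean 0.12, camera direction down, adjusted p = 0.760). Cd36 passed over all genes in 3 of 23 other fits. 

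Camera called the 2 extracellular matrix lists with direction up and the G2/M list with direction down. Fibrillar and associated matrix genes gave 1 of 19 over all genes and 12 adjusted over the list alone (median 1.38, adjusted p = 1.11e-09, adjusted p = 0.455 with an estimated correlation). The called gene was Fbn1, encoding fibrillin 1, with a 3.67-fold rise, and Col5a1 stood at 117 and 385 CPM and Bgn at 172 and 752 CPM. Basement membrane genes gave 1 of 15 over all genes and 6 adjusted over the list alone (median 0.95, adjusted p = 1.19e-08, adjusted p = 0.355 with an estimated correlation), the called gene being the laminin gene Lamb2 with a 3.58-fold rise and Col4a5 standing at 10.6 and 58.8 CPM. Col4a5 passed without cHet8 (log2 3.08, adjusted p = 0.0347) and without cKO9 (0.0462). With the mesenchyme score as covariate both matrix calls ended, with the direction down for fibrillar matrix (median 0.12, adjusted p = 0.448) and up for basement membrane (median 0.33, adjusted p = 0.113). For fibrillar matrix this says little, because 11 of the 20 mesenchyme genes belong to that list. All 22 tested G2/M genes had negative log2 values (median −0.86, adjusted p = 9.49e-09, adjusted p = 0.455 with an estimated correlation), with 0 called over all genes by edgeR and 6 lower adjusted over the list alone. Among them were Nusap1 (32.1 and 12.1 CPM), Cdk1 (19.4 and 10.7 CPM), Birc5 (15.3 and 8.29 CPM) and Cenpa (27.3 and 15.5 CPM). Each of these named genes passed over all genes in 1 of 23 other fits. The 19 G1/S genes gave 0 calls under both adjustments (median −0.07, adjusted p = 0.459), with Uhrf1 at 19.9 and 12 CPM. The G1/S list passed with direction down with the olfactory covariate (adjusted p = 0.0367), mesenchyme scaling (0.00336) and the mesenchyme covariate (median −0.42, adjusted p = 5.21e-06, adjusted p = 0.165 with an estimated correlation). Markers of macrophages and of olfactory cells were lower in cKO beside the mitotic genes.

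**Figure D2:**
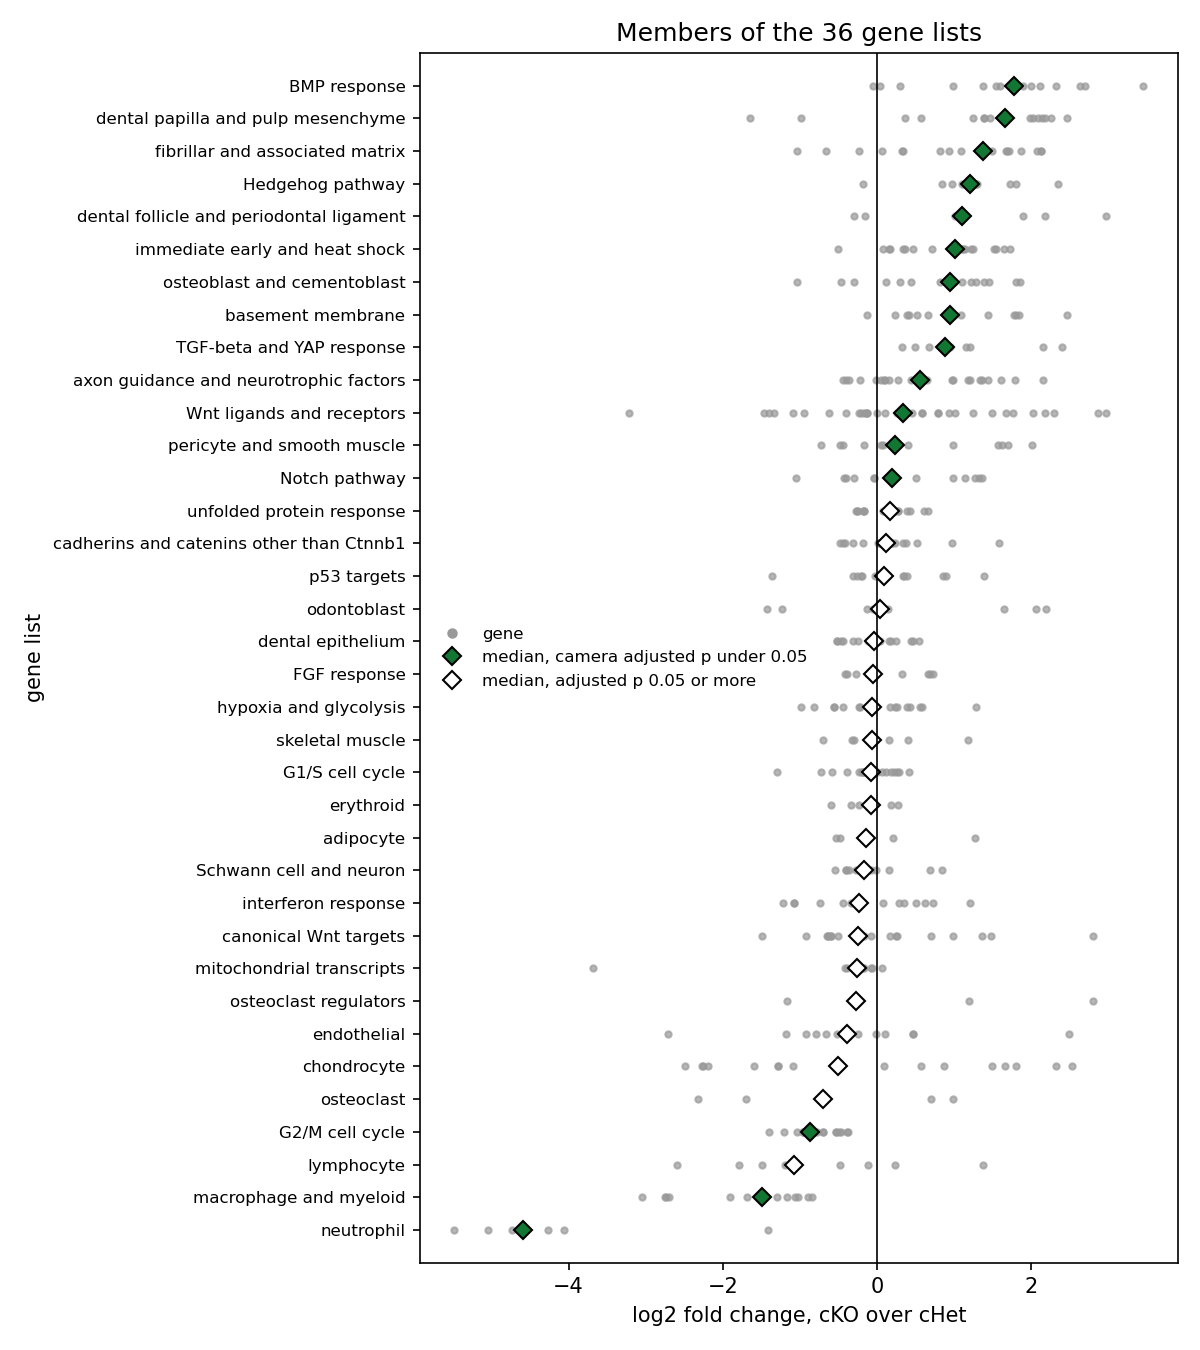
Log2 fold change of every tested member of the 36 fixed lists (grey points) and the median of each list (diamonds, filled green where the camera adjusted p at the preset correlation is under 0.05). The medians run from −4.59 for neutrophil markers to 1.78 for BMP response, and the canonical Wnt targets spread on both sides of 0 around −0.24.

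Immediate early and heat shock genes, which respond to tissue dissociation, passed camera with direction up (median 1.01, adjusted p = 2.53e-08, adjusted p = 0.455 with an estimated correlation). None of 20 was called over all genes by edgeR and 11 were higher adjusted over the list alone, with Egr1 at 1091 and 3179 CPM, Fosb at 48.7 and 162 CPM and Socs3 at 142 and 444 CPM. Over all genes Egr1 passed in 4 of 22 other fits, and Fosb in 2 and Socs3 in 4 of 23. The list's call ended with the mesenchyme score as covariate (median 0.10, adjusted p = 0.973). Notch pathway genes gave 1 of 13 over all genes and 4 adjusted over the list alone (median 0.20, adjusted p = 0.0315, adjusted p = 0.455 with an estimated correlation). The called gene was the ligand gene Jag1, which rose from 23.1 ± 4.86 to 59.3 ± 20.1 CPM. The Notch call ended with DESeq2 (adjusted p = 0.0556), voom (0.0888) and the stricter filter (0.0550), with mesenchyme scaling (0.0527), without cHet11 and cKO9 (0.142), without cHet12 and cHet8 (0.0501), without cHet11 alone (median −0.0307, adjusted p = 0.109) and with the mesenchyme score as covariate (median 0.0768, adjusted p = 0.473). Lists that did not pass camera were FGF response (adjusted p = 0.949, direction up with a median of −0.05 and a mean of 0.11, 0 of 10 called by edgeR, with Etv5 at 89.8 and 68.8 CPM), p53 targets (0.675, 0 of 14, 1 adjusted over the list alone, with Plk2 at 75.0 and 196 CPM), interferon response (0.612, 0 of 15, with Ddx60 at 11.4 and 4.89 CPM) and hypoxia and glycolysis (0.973, 0 of 17, with Slc2a1 at 46.6 and 34.5 CPM). Over all genes Etv5, Ddx60 and Slc2a1 each passed in 1 of 23 other fits and Plk2 in 3. The unfolded protein response list did not pass either (0.305) and held 1 called gene of 15. Osteoclast regulators gave 0 of 5 by edgeR and 2 adjusted over the list alone, Tnfsf11 (0.779 and 5.47 CPM) and Csf1 (15.4 and 35.1 CPM), with a median of −0.27, a mean of 0.45, direction up and an adjusted p of 0.572. The median of these regulators ran from −1.33 to 0.57 over 22 refits. Over all genes Tnfsf11 passed in 1 of 23 other fits and Csf1 in 2. The 11 mitochondrial transcripts, a measure of RNA quality, gave no calls (median −0.26, adjusted p = 0.0774), and their share of counts was 0.297% ± 0.0570 in cHet and 0.231% ± 0.0275 in cKO (exact p = 0.0857). The mitochondrial list passed with direction down without cHet14 (adjusted p = 0.00366), cHet8 (0.0457) or cKO7 (0.0170), and also with DESeq2 (0.0330), voom (0.0483), no filter (0.0400) and the olfactory covariate (0.0367).

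Markers of cell types outside the sorted population were abundant in every library. Omp, the marker of mature olfactory sensory neurons, was present at 1739 to 3940 CPM, and olfactory receptor genes took 1.07% ± 0.197 of all counts in cHet and 0.689% ± 0.170 in cKO (exact p = 0.0857). In cKO9 the share was 0.938%, inside the cHet range of 0.897% to 1.27%. Between 824 and 1181 olfactory receptor genes were detected per library. The labels do not account for these transcripts, so the share of RNA from apical papilla cells in each library is not known. The added list of 15 olfactory neuron genes had a negative log2 value in every member (median −0.47) and its score was 0.44 lower in cKO (exact p = 0.0857). Supporting cell and gland genes of the same epithelium had a median of −0.75, with Cyp2g1 at 457 ± 123 and 209 ± 134 CPM, and a score 0.98 lower (exact p = 0.0857). Enamel-forming ameloblasts were represented by Ambn at 1374 to 6863 CPM and Amelx at 463 to 3284 CPM, with a score difference of 0.21 (exact p = 0.686). General mesenchyme genes, 12 of 20 of which also belong to a fixed list, had a median of 1.56, with Prrx1 at 26.5 ± 11.2 and 91.9 ± 19.0 CPM (adjusted p = 0.0455).

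**Figure D3:**
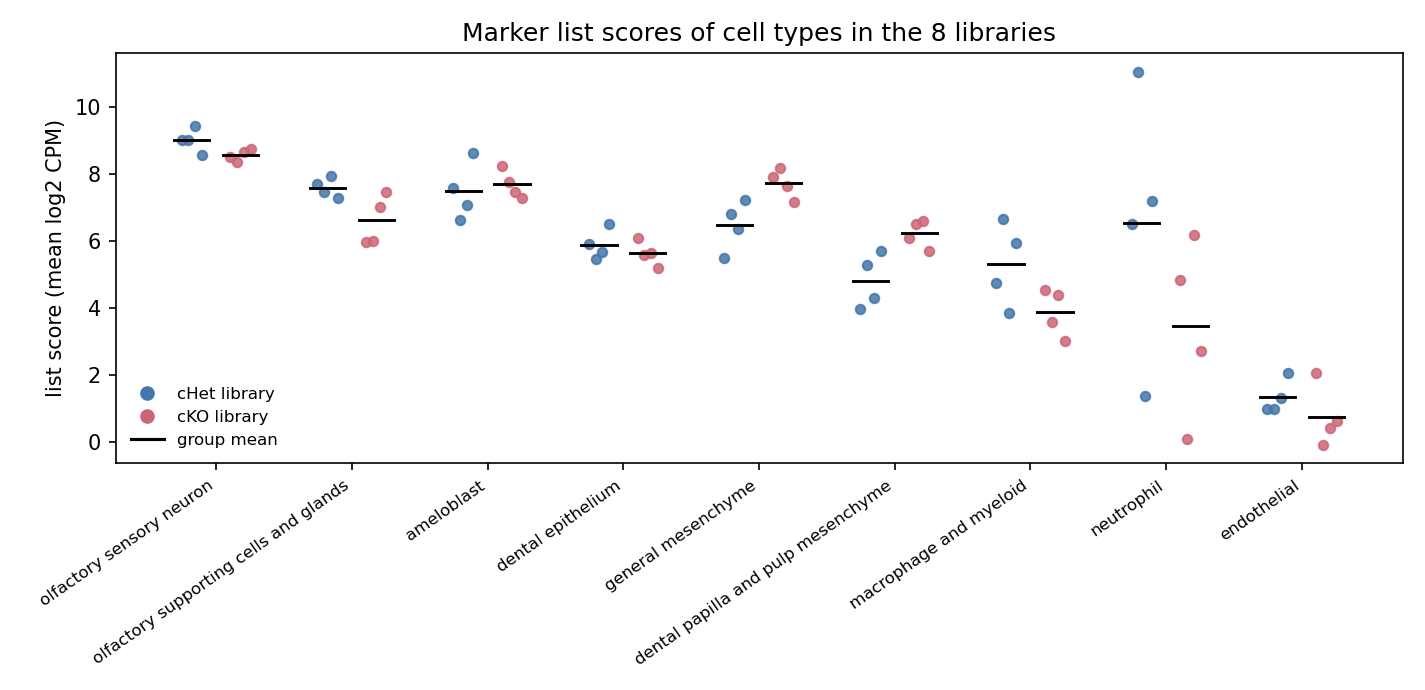
Scores (mean log2 CPM) of 9 marker lists in each library, with points for libraries coloured by group and a bar at each group mean. Olfactory neuron scores lie between 8.36 and 9.41 in all 8 libraries, and the neutrophil score of cHet12 stands at 11.04.

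Of the fixed lists of other cell types, macrophage and myeloid genes passed camera with direction down (12 of 12 negative, median −1.49, adjusted p = 4.91e-06, adjusted p = 0.455 with an estimated correlation), with 0 of 12 called over all genes by edgeR and 7 lower adjusted over the list alone. Lyz2 stood at 796 ± 1117 and 96.3 ± 72.4 CPM and Adgre1 at 24.0 ± 12.4 and 7.47 ± 3.04 CPM. Over all genes Adgre1 passed in 1 of 23 other fits and Lyz2 in 0. Lyz2 reached 2455 CPM in cHet12 against 56.3 to 436 CPM in the other cHet libraries, and its log2 value moved from −3.05 to −1.34 without cHet12. The macrophage call ended when cHet12 and cHet8 were both left out (median −0.42, adjusted p = 0.182). Neutrophil genes also passed with direction down (0 of 8 called by edgeR under both adjustments, median −4.59, adjusted p = 0.00680, adjusted p = 0.639 with an estimated correlation). The neutrophil call ended with voom (median −1.98, adjusted p = 0.308), without cHet12 (median −1.89, adjusted p = 0.111) and without cKO9 (median −4.24, adjusted p = 0.0837). It also ended with mesenchyme scaling (0.343), without cHet11 and cKO9 (0.0574) and without cHet12 and cHet8 (median −0.92, adjusted p = 0.595). S100a8 reached 4461 CPM in cHet12 against 4.28 to 283 CPM in the other 7 libraries, and passed over all genes in 1 of 23 other fits. Pericyte and smooth muscle genes passed with direction up (1 of 12 called and 4 adjusted over the list alone, median 0.24, adjusted p = 0.00562, adjusted p = 0.455 with an estimated correlation). The called gene was Cspg4, a pericyte surface proteoglycan, at 12.6 and 37.2 CPM, with Abcc9 at 11.5 and 46.7 CPM. The pericyte call ended with the mesenchyme score (median −0.0250, adjusted p = 0.753) or the olfactory score as covariate (median 0.0501, adjusted p = 0.511). Its median ran from −0.92 to 0.71 over 22 refits, highest without cHet12 and cHet8. The endothelial list did not pass (adjusted p = 0.410), nor did lymphocyte (0.0708), erythroid (0.553), dental epithelium (0.558), Schwann cell and neuron (0.444), skeletal muscle (0.949) and osteoclast markers (0.817). The endothelial list passed with direction down without cKO14 (adjusted p = 0.0182), and the lymphocyte list without cHet11 (0.0346), cHet14 (0.00645), cKO14 (0.0316) or cKO15 (0.0129) and without a filter (0.00471). With the olfactory and mesenchyme covariates, camera called 3 of these lists down: endothelial (0.0222 and 0.0155), lymphocyte (3.62e-05 and 2.19e-04) and dental epithelium (0.00318 and 0.0112). Their adjusted p with an estimated correlation lay between 0.165 and 0.582 in the same fits. None of these 7 lists held a called gene over all genes by edgeR, and 1 endothelial gene, Erg (1.74 and 9.79 CPM), was higher adjusted over the list alone. Pecam1 stood at 9.69 and 5.62 CPM, Ighm at 17.5 and 5.07 CPM, Epcam at 437 and 321 CPM, Mylpf, in a muscle list with a median of −0.07 and a mean of 0.07, at 3.31 and 2.65 CPM and Mmp9 at 290 and 57.9 CPM. Over all genes Erg passed in 3 of 23 other fits, Ighm and Epcam each in 1, and Pecam1, Mylpf and Mmp9 in 0. Mmp9 stood at 899 CPM in cHet12, and its log2 value moved from −2.32 to −0.58 without that library.

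**Figure D4:**
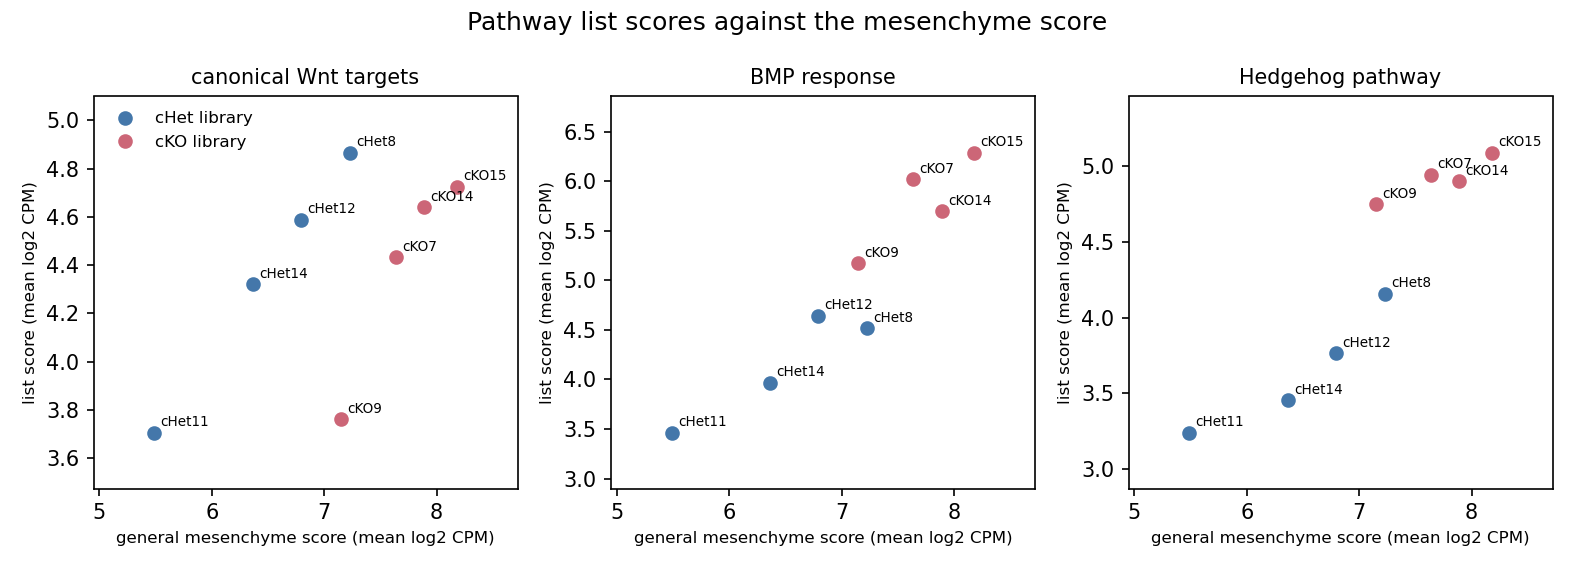
Scores (mean log2 CPM) of 3 pathway lists against the score of the general mesenchyme list, 1 point per library, coloured by group and named. At similar mesenchyme scores, 7.23 in cHet8 and 7.15 in cKO9, the canonical Wnt target score was 4.87 and 3.76, the BMP response score 4.52 and 5.18 and the Hedgehog score 4.16 and 4.75. These values compare 1 library with 1 library. The Wnt score of cHet8 was the highest of all libraries. That of cKO9 was the lowest in cKO, where the others lay between 4.43 and 4.73.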

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

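All tests of explanations in this part were chosen after the results had been seen, while the rule for outlying libraries was fixed beforehand. For differences at a constant mesenchyme score, the exact p exchanged group labels while the mesenchyme score of each library stayed in place. That score differs between the groups (6.47 in cHet, 7.71 in cKO), so these p-values are approximate and may be too small. Of 266 groups of 4 libraries examined, 13 held a library whose gap to its neighbour exceeded 0.829 of the group's range, close to the 5% that chance gives. In cHet, cHet11 stood apart with the most detected genes (ratio 0.877) and the lowest osteoblast and cementoblast score (0.896), interferon score (0.932), Bgn (0.899) and Cspg4 (0.926). cHet8 stood apart with the highest pericyte score (0.869) and Dkk1 (0.891). In cKO, cKO9 had the lowest Notum (0.842), Nkd1 (0.867) and Atoh8 (0.830). cKO15 had the highest Fzd2 (0.857) and Jag1 (0.846) and the lowest Adgre1 (0.838).

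The count of Ctnnb1 was not lower in the libraries labelled cKO. Libraries exchanged between the groups would hide a fall of 1.5-fold only if some other grouping showed one, and the largest difference over the 35 splits of the 8 libraries was 0.34 on the log2 scale, below the 0.58 that such a fall needs. A smaller fall in the whole-gene count would escape this test. Reads from undeleted exons or from cells without the deletion could make it smaller, so an exchange of libraries is not excluded. Reads from cells without the deletion stay open as a hypothesis. Scaled to mesenchymal genes, Ctnnb1 lay 0.10 above the median change of all genes (SE 0.41), which neither requires nor excludes them. Reads from undeleted exons may also account for it, since even the lowest cKO library held 229 CPM of the gene and counts per exon were not analysed here.

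The rises outnumbered the falls by far, and the grouping by genotype was the only 1 of the 35 splits that called any gene: 244 genes, 232 in the larger and 12 in the smaller direction, against 0, 0 and 0 in the highest of the other splits, so that only 1 split, the real one, was as large for each count, which is 1 outcome seen 3 ways, since each other split mixes the genotypes. A smaller share of olfactory RNA as the whole cause would raise all other cell types alike, but the papilla score minus the mean of the 10 other cell type scores was 2.16 higher in cKO (1.61 ± 0.53 and 3.77 ± 0.67, exact p = 0.0286), and 1.78 higher with macrophage and neutrophil scores left out (exact p = 0.0286). As a part of the cause it stays open, since with the olfactory score as covariate 0 genes were called, the median log2 change of the 232 genes going from 1.94 ± 1.18 (SD over genes) to 1.58 ± 1.11 and their median SE from 0.31 to 0.39. A larger mesenchymal share cannot be told apart from a change within the cells: the Hedgehog list passed fry with the mesenchyme score as covariate (adjusted p = 0.0111) but not camera with an estimated correlation (adjusted p = 0.0685), its median was 0.0106 ± 0.73 (SD over genes) with libraries scaled to mesenchymal genes, and at a constant mesenchyme score the papilla score differed by 0.25 (exact p = 0.400), BMP response by 0.71, Hedgehog by 0.70 (0.62 to 0.91 when each library was left out) and TGF-beta and YAP by 0.43 (each exact p = 0.0286, 0.0857 adjusted over 36 lists). The 232 genes, chosen because they had risen, had a median of 1.20 ± 1.13 with the mesenchyme covariate, where 6 were called, and of 0.72 ± 1.24 with mesenchyme scaling, where 44 were negative, and a genotype effect on the cells or on which cells were sorted remains possible.

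The number of lists called by camera is weaker evidence. The real grouping called 16 lists, the highest other split 24, and 12 of the 35 splits called as many, so chance could not be excluded for that count.

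Canonical Wnt targets did not fall as a list although the gene deleted is their activator. A candidate explanation is a fall hidden by the larger mesenchymal share: with the mesenchyme score as covariate the list was lower (adjusted p = 0.00897 by fry), and at a constant score its mean differed by −0.91 (exact p = 0.0286, 0.0857 adjusted over 36 lists), between −1.0 and −0.71 when each library was left out. Other settings gave less, with a median of −1.47 under mesenchyme scaling against −1.30 for all genes (camera adjusted p = 0.0656) and an adjusted p of 0.555 by fry with the olfactory covariate. In the mesenchyme covariate fit Notum had a log2 value of −2.43 (SE 0.30), Nkd1 of −1.90 (SE 0.25) and Lef1 of −1.12 (SE 0.26), of which none passed over all genes (adjusted p = 0.0962, 0.109 and 0.390). A shift that the covariate gives to lists following the mesenchyme score cannot be told apart from it, since the 14 other such lists that share no gene with it had a median difference of −0.17 (SD 1.31) and 4 of them, interferon response (−0.94), lymphocyte (−2.07), macrophage (−2.56) and neutrophil (−3.84), lay below the Wnt list while the other 10 lay between −0.43 and 0.71, and the mesenchyme scores, from a list drawn up after the data had been seen, overlap between the groups only in cHet8 and cKO9.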

How the results depend on the processing

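No paired analysis was possible because the table's columns carry none of the replicate numbers in the labels. The covariate and scaling settings and the omissions of 2 libraries were chosen after the data had been seen, and the cause of each change was not tested unless given. Genes higher and lower in cKO, 232 and 12, became 1704 and 853 with DESeq2, 1281 and 271 with voom, and 704 and 62 at an adjusted p under 0.10. They became 10 and 0 in the test against 1.5-fold (1608 at an unadjusted p under 0.05), 0 and 0 with the olfactory covariate (1327 unadjusted, not far above the share of 0.05 of tested genes that chance gives), 5 and 4 with mesenchyme scaling and 6 and 3 with the mesenchyme covariate. They were 609 and 32 without cHet11 and cKO9, and 91 and 0 without cHet12 and cHet8. Lower genes alone moved to 5 without a filter and 7 with robust dispersions. The other 7 fits fixed beforehand gave 179 to 293 higher genes. Of the 232, DESeq2 and voom called all 232 higher, and mesenchyme scaling gave a negative value to 44, when the median of all genes moved to −1.30 (−0.12 with library size alone). Leaving out 1 library gave 0 to 816 higher and 0 to 144 lower genes, fewest without cHet12, cHet14 or cKO14 (0 and 0) and most without cKO9; fewer libraries lower the power, but cKO9 shows that the count also rests on which are used. Ctnnb1 turned to −0.0566 with the olfactory covariate, −1.20 with mesenchyme scaling and −0.13 with the mesenchyme covariate, and Lef1 to −0.23, −0.83 and −1.12 in the same order, with a range of −0.0289 to 0.555 when 1 library was left out. Lists called, 16, fell to 0 with an estimated correlation and 4 with fry. For canonical Wnt targets, camera's direction turned to up with voom (median −0.13) and without cHet12 and cHet8 (0.0257), and passed as down with the olfactory (−0.26) and mesenchyme covariates (−1.003); leaving out 1 library gave medians of −0.307 to −0.0950, with the direction up without cHet12, cHet8 or cKO9, and adjusted p over all 22 refits from 9.20e-16 to 0.943. The odontoblast list turned to down with the mesenchyme covariate (−0.58) and ranged from −0.0710 to 0.63 when 1 library was left out, passing without cHet8 (0.63). The osteoblast and cementoblast list kept its median of 0.95 but lost its call with an estimated correlation (adjusted p = 0.545) and with fry (0.203), and turned to down with the mesenchyme covariate (−0.12). The mesenchyme covariate also ended the calls of 7 lists: Wnt ligands and receptors, follicle, Notch, fibrillar matrix, basement membrane, immediate early, and pericyte. BMP response, Hedgehog, TGF-beta and YAP, axon guidance, papilla and G2/M lists were called in the same direction in all 22 refits with camera at the preset correlation. Camera's direction is relative to all other genes, and the sign of the medians was not kept throughout. With mesenchyme scaling the medians were 0.57 for papilla, 0.47 for BMP response and 0.0106 for Hedgehog. They were negative for TGF-beta and YAP (−0.27) and axon guidance (−0.68), as for G2/M (−2.07). With the mesenchyme covariate camera also called down osteoclast regulators (0.0222), interferon response (1.02e-04), hypoxia (0.0404) and osteoclast markers (0.0493). Without cKO9, Wnt9a, Cthrc1, Sparc, Dlx2, Postn, Mkx, Sox9, Col9a2, Cd36, Tgfbi, Smo, Plk2, Col5a1, Bgn, Cdh11, Egr1, Socs3, Erg and Abcc9 also passed. The share of variance of the leading component was kept with all genes (27.3%). Total counts were 44444033 to 50051392 per library. Single molecules were not tagged, so these totals do not show how many molecules were sampled. Whether depth or the spread between libraries limited the calls of the named genes was not tested.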

Other observations

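Tests in this part were chosen after the data had been seen. Genes called with the mesenchyme score as covariate differed between groups after a common slope on that score was fitted. The scores overlap between the groups only in cHet8 and cKO9, so the fit reaches beyond the shared range. In that fit 6 genes were higher in cKO, the 3 named among the largest rises, Kif26b (log2 3.01, SE 0.22), Col25a1 (2.88, SE 0.19) and Bmp2 (2.06, SE 0.21), together with Tnc (1.51, SE 0.15), the phosphatase gene Ptpru (2.13, SE 0.17) and Megf6 (1.94, SE 0.18). The 3 lower genes were Coch (−2.56, SE 0.14), the sphingomyelinase gene Smpd3 (−2.59, SE 0.23) and Lum (−2.29, SE 0.23), which is itself a member of the mesenchyme list, rises with that score inside both groups and had a log2 value of −0.66 without the covariate. Their adjusted p lay between 0.00401 and 0.0386 with edgeR. Cxcl12 had a log2 value of 1.25 (SE 0.29) in that fit, against 2.47 (SE 0.46) without the covariate, and did not pass (adjusted p = 0.401).

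Olfactory receptor genes were surveyed as a family because their presence was unforeseen in tooth cells. Of 1044 tested members, 769 had a negative log2 value (median −0.53), 2 were called higher and 2 lower. No label mentions nasal tissue, and whether the dissection, the barcodes or the match of the table to these samples accounts for the transcripts was not tested. None of the 23 genes of the olfactory lists belongs to a fixed list. Of the 7 ameloblast genes, 5 also belong to a fixed list.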
